A study of Arabidopsis thaliana with 12 samples.

How the data were processed

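Small RNA libraries had been made from total RNA with the TruSeq small RNA kit, from meiocytes isolated from floral buds and from whole seedlings. The submitters' processing notes name cutadapt 3.4, Bowtie and DESeq2, and the genome build TAIR10. Versions of Bowtie and DESeq2, the number of mismatches and the treatment of reads that map to several places are not given in the sources used here. Each library was deposited as 1 table of raw read counts in 100-base bins of the genome, with 9 columns. Total counts ran from 4399628 to 9934560 reads per library. The columns carry no header and were taken as read lengths of 18 to 26 nt, because 100 of 120 annotated 21 nt mature microRNAs had most reads in the column taken as 21 nt. For 22 nt mature microRNAs this held for 6 of 16, with 6 others highest in the column taken as 21 nt. Strand is not recorded in the tables.

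The 1196681 bins were placed on the TAIR10.1 reference annotation after the number of bins of each chromosome had been compared with the reference length. Chromosomes 1 to 5 and the chloroplast matched. The mitochondrion had 3670 bins where the reference length gives 3679, so mitochondrial genes were not used. Counts of the 9 lengths were summed per bin. Gene values are sums over the bins that touch a gene, so that neighbouring or overlapping genes can share reads, and such genes are named as sharing reads. The annotation used here does not mark transposable element genes, which fall in its pseudogene class or outside genes. The 45S rDNA intervals were set around the annotated 18S genes on chromosomes 2 and 3, from 4000 bases before to 8000 bases after the start of each gene.

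Bins and genes were tested with edgeR 4.0.16 in R 4.3.3, using quasi-likelihood F-tests with robust dispersions, TMM (trimmed mean of M-values) factors and filterByExpr with a minimum count of 10. All 12 libraries were fitted together as 6 group means, which leaves 6 residual degrees of freedom for each feature and a median of 14.4 prior degrees of freedom across bins. The filter kept 39606 bins and 12259 genes. P-values are two-sided, adjusted by the method of Benjamini and Hochberg within each comparison, and a feature was called at an adjusted p under 0.05. Log2 fold changes are given with their standard error (SE). Fold changes in the text are ratios of the reads of a group, summed over its 2 libraries and divided by their TMM-scaled library sizes; levels are TMM-scaled CPM (counts per 1e6 scaled reads). Where 1 group had no read, the fold is a lower bound computed with 3 counts over that group. Where it had 1 to 3 reads, the ratio is given with its 95% counting interval. Such intervals and bounds cover counting error only.

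Sets of features were tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01, with the estimated correlation and fry beside it. The 9 classes of bins were microRNA (MIR) genes, trans-acting siRNA (TAS) genes, pseudogenes, protein-coding genes, structural RNA genes, other non-coding genes, intergenic bins, pericentromeres and chromosome arms. The 8 gene lists were conserved MIR genes, other MIR genes, TAS genes, RNA-directed DNA methylation (RdDM) machinery (to which POL2A, a replication enzyme, had been added as a mutated gene), known RdDM targets, genes of meiotic recombination, tapetum markers and green tissue markers. Lists, comparisons, most alternative settings and the rule for naming genes were fixed before the data were examined. By that rule the text names, for each mutant against wild type (WT) and for the tissue comparison, the 10 genes that rose and the 10 that fell with the smallest p among called genes whose 2 libraries of 1 group both lay above those of the other. It also names 3 and 3 such intergenic regions, 3 and 3 genes for the direct mutant comparisons and the interactions, every called list gene or a summary of them, the listed genes with the most reads among those not called, and POL2A, SUVH2 and SUVH9. Regions are called bins of the same direction merged within 200 bases around an intergenic bin, so that a region can reach into a gene.

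TMM factors of the bins ran from 0.479 to 3.129, so that the direction of many changes depends on the scaling. Those of the genes were computed apart and ran from 0.61 to 1.947, so folds of genes and of regions are on different scales. Alternative scalings were library size alone, size factors from MIR genes alone (MIR scaling) and DESeq2 1.42.0 with its own size factors. Another, with rDNA, organelle and structural RNA bins removed, was added after the data had been seen, as were fits on 24 nt reads alone and on 21 to 22 nt reads alone, the sharing of calls between tissues, and counts of loci, which are tested bins joined when at most 10 bins apart. MIR scaling holds the summed MIR reads level, so it cannot show a change common to MIR genes. For these genes it is not an independent check. The test was tried on simulated counts with the depths and mean levels of these libraries and a dispersion of 0.1, where the common dispersion fitted here was 0.116 for bins and 0.0785 for genes. Of 100 bins changed 4-fold, 23% to 45% were called, and of 100 changed 2-fold, 0% to 1%. For genes these ranges were 53% to 66% and 0% to 4%, with 0 to 5 false calls per comparison. The simulation gave all groups the same dispersion. Between real replicates the chi-square of bin counts per degree of freedom was 3.03 in WT and pol2a meiocytes. It was 7.16 and 12.5 in WT and pol2a seedlings, and 18.4 in suvh2suvh9 meiocytes and seedlings. The false calls of the groups with more spread are therefore not known from it. Shares per library were compared with exact two-sided permutation tests, which in a design of 2 against 2 cannot go below p = 0.33. P-values measure the spread between these samples, and whether seedling replicates came from separately grown plants is not stated. Shares and figures were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.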

Results

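Small RNAs of male meiocytes and seedlings were compared between WT plants and 2 mutants. One, pol2a-1 (pol2a below), affects the catalytic subunit of DNA polymerase epsilon, and the other, suvh2suvh9, lacks a pair of related proteins of RNA-directed DNA methylation. Each of the 6 groups had 2 libraries, so n = 2 per group in every comparison. Replicates were not copies of each other, with Pearson correlations of 0.838 to 0.896 between log2 CPM values of bins.

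The first question was what the libraries held. In WT meiocytes 53.2% of all reads (SD 1.91, n = 2) were 23 to 24 nt long and lay in the nuclear genome outside rDNA and structural RNA genes, the place and size of siRNAs of the RdDM pathway. In WT seedlings this share was 22.9% (SD 3.96). MIR genes took 0.556% (SD 0.0424) of reads in WT meiocytes and 6.09% (SD 1.66) in WT seedlings, and chloroplast reads took 1.08% (SD 0.00809) and 16.5% (SD 0.712). Chloroplast reads took 2.08% (SD 0.187) in pol2a meiocytes and 2.03% (SD 0.59) in suvh2suvh9 meiocytes, and 16.7% (SD 0.0928) and 23.2% (SD 3.97) in the seedlings of these mutants. The 45S rDNA took 25.9% (SD 0.675) of reads in WT meiocytes, 61.2% (SD 0.225) in pol2a meiocytes and 25.9% (SD 0.365) in suvh2suvh9 meiocytes. In seedlings it took 40.2% (SD 5.74) in WT, 44.4% (SD 7.28) in pol2a and 59.8% (SD 1.65) in suvh2suvh9. Intergenic reads made up 55.9% (SD 0.745) in WT meiocytes, 30.3% (SD 0.319) in pol2a meiocytes and 54.2% (SD 2.22) in suvh2suvh9 meiocytes, and 22.4% (SD 2.66), 21.8% (SD 2.85) and 9.25% (SD 0.531) in the seedlings of WT, pol2a and suvh2suvh9. Counted per 20 to 22 nt MIR read, the 23 to 24 nt reads were 117 (SD 12.8) in WT meiocytes, 115 (SD 3.08) in pol2a meiocytes and 133 (SD 7.53) in suvh2suvh9 meiocytes. In seedlings they were 4.22 (SD 0.395) in WT, 5.61 (SD 0.221) in pol2a and 1.82 (SD 0.0397) in suvh2suvh9. Where 2 groups did not overlap in a share, the exact permutation test gave p = 0.33, its lowest possible value.

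**Figure D1:**
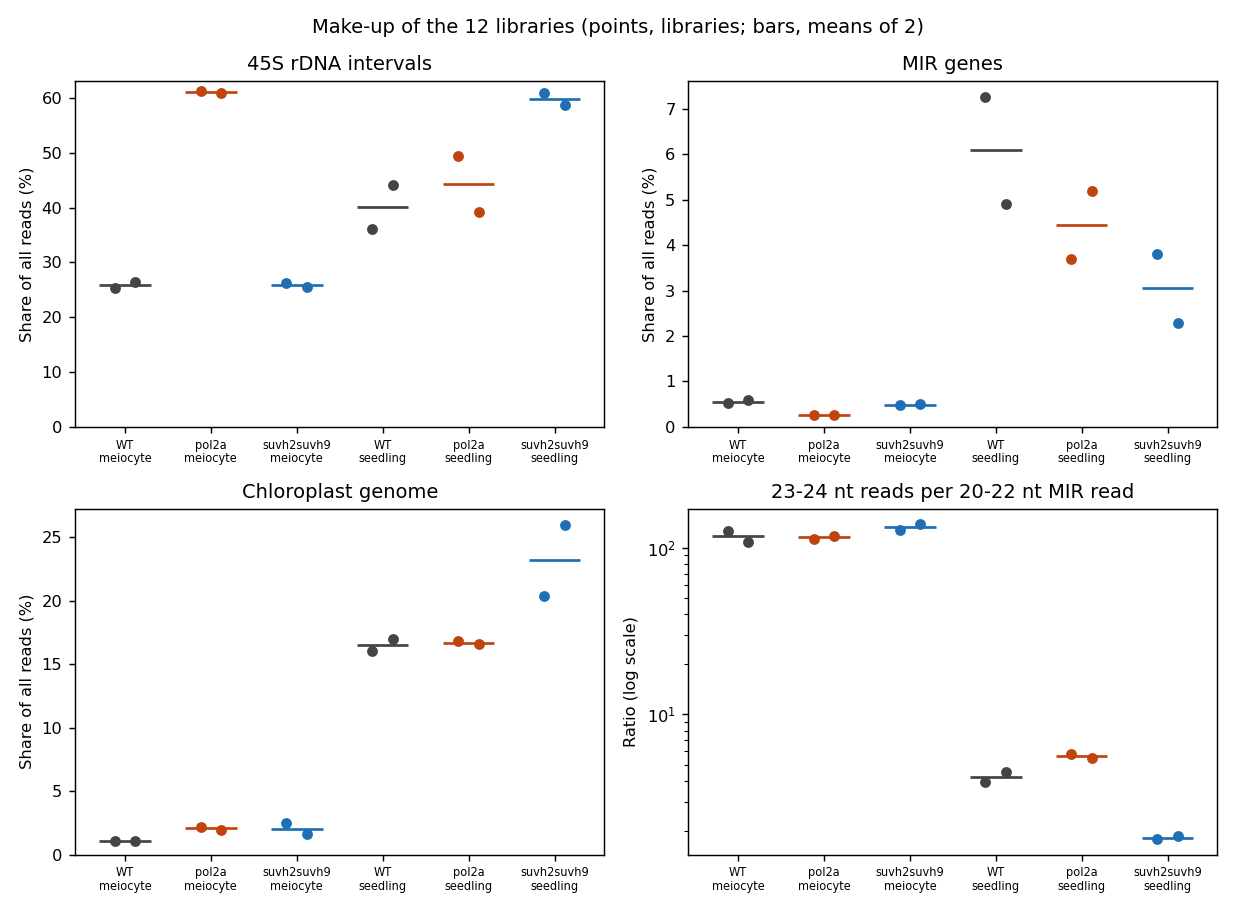
Shares of all reads in the 45S rDNA, in MIR genes and in the chloroplast, and 23 to 24 nt reads per 20 to 22 nt MIR read (log axis). Points are libraries and bars are means of 2.

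The length of nuclear reads outside rDNA and structural RNA genes also differed between groups. Reads of 24 nt made up 59.3% (SD 2.02, n = 2) in WT meiocytes, 40.2% (SD 2.45) in pol2a meiocytes and 47.4% (SD 8.29) in suvh2suvh9 meiocytes. Reads of 23 nt made up 15.1% (SD 0.0976), 27.2% (SD 0.761) and 23.7% (SD 3.42). In suvh2suvh9 seedlings 24 nt reads made up 22.4% (SD 5), against 43.5% (SD 0.448) in WT seedlings and 46.7% (SD 0.987) in pol2a seedlings. Reads of 18, 19 and 20 nt made up 6.52%, 8.57% and 12.9% (SD 2.13, 1.12 and 2.03) in suvh2suvh9 seedlings, against 2.66%, 3.09% and 5.72% (SD 0.293, 0.0608 and 0.106) in WT seedlings. The 1000 bins with most 24 nt reads held 69.7% (SD 0.293) of such reads in WT meiocytes and 23.3% (SD 0.753) in WT seedlings, so that siRNAs of meiocytes came from fewer places.

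**Figure D2:**
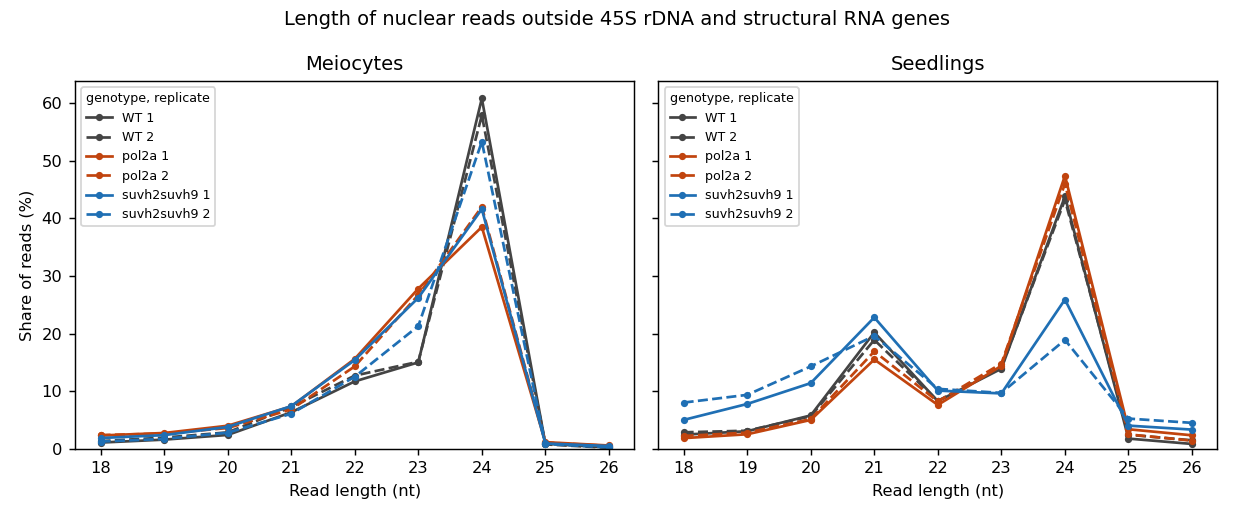
Length of nuclear reads outside the 45S rDNA and structural RNA genes. Solid and dashed lines are the 2 libraries of a group.

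The mutated genes came next, with the limit that small RNA reads at a gene do not measure its mRNA. At TIL1, the gene that encodes POL2A, WT meiocytes had 28 and 19 reads and pol2a meiocytes 6 and 13, a log2 value of -0.36 (SE 0.54; adjusted p = 0.827, edgeR). In pol2a seedlings the log2 value at TIL1 was -0.65 (SE 0.62; adjusted p = 1). SUVH2 had 7 and 8 reads in WT meiocytes, and 5 and 2 in suvh2suvh9 meiocytes. SUVH9 had 195 and 99 reads in WT seedlings, 13 and 13 in pol2a seedlings, and 18 and 4 in suvh2suvh9 seedlings. Small RNAs at SUVH9 were 17.9-fold lower in pol2a seedlings (log2 -4.14, SE 0.51; adjusted p = 1.18e-06) and 10.4-fold lower in suvh2suvh9 seedlings (log2 -3.43, SE 0.52; adjusted p = 1.37e-06). In meiocytes SUVH9 had 3 and 1 reads in WT, 3 and 1 in pol2a, and 4 and 3 in suvh2suvh9.

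How do WT meiocytes differ from WT seedlings? MicroRNAs of the MIR159 family, which act on MYB factors, were among the losses with the smallest p in meiocytes, with MIR159B 171-fold lower (log2 -7.40, SE 0.46), MIR159A 124-fold lower (log2 -6.93, SE 0.45) and MIR159C 67.3-fold lower. MIR163 was 252-fold lower and TAS1A 108-fold lower. Small RNA fragments of photosynthesis genes fell as well, with RCA, which encodes Rubisco activase, 69.5-fold lower (log2 -6.11, SE 0.45) and CAB2 76.9-fold lower. Among the gains, AT2G36040 was 1450-fold higher (log2 10.48, SE 0.58; adjusted p = 3.76e-17), AT5G42265 765-fold and AT3G11680 489-fold. AT1G43897 (865-fold), AT5G04267 (676-fold), AT3G08295 (513-fold), AT4G07765 (374-fold) and AT4G17590 (304-fold) also rose, as did AT2G08405 (461-fold) and AT2G30615 (451-fold), which share reads. AT5G38850 was 76.5-fold lower, and the losses in MIR3932B (1110-fold), AT5G03553 (129-fold) and MIR5996 (93.5-fold) concern genes that share reads with others. Fragments of meiotic genes rose, with DMC1, the meiotic recombinase, 26.7-fold higher (log2 4.67, SE 0.57; adjusted p = 1.02e-08), ZYP1a 35.8-fold (77 against 3 reads; interval 11.8 to 177), ZYP1b 50.2-fold (interval 8.46 to 2040) and ASY1 at least 24.6-fold (53 reads against 0).

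By list, 62 of 85 tested conserved MIR genes were called lower and 3 higher in meiocytes, or 69 and 3 adjusted over the list alone (camera adjusted p = 2.33e-17; adjusted p = 0.0294 with an estimated correlation; median log2 -3.32). MIR scaling gave 39 lower and 12 higher there. MIR157D (log2 8.24, SE 0.49), MIR156A (2.91, SE 0.38) and MIR166G (2.40, SE 0.73) were the conserved genes that rose. Of 141 other MIR genes 60 were lower and 31 higher, or 61 and 31 adjusted over the list alone (camera adjusted p = 0.0137; adjusted p = 0.487 with an estimated correlation), and their median of -1.04 turned to 1.04 under MIR scaling. All 8 green tissue markers were lower (camera adjusted p = 6.09e-12; 0.0294 with an estimated correlation), from CAB1 at 19.5-fold and RBCS1A at 20.8-fold to RBCS2B at 206-fold (interval 70.2 to 1000). Of 8 TAS genes 6 were lower and 2 higher (camera adjusted p = 7.02e-05; adjusted p = 0.154 with an estimated correlation). TAS1C was 6.29-fold lower (log2 -2.66, SE 0.38), a call lost under MIR scaling (-0.58). TAS3b was 2.95-fold higher, and TASIR-ARF 2.2-fold higher (log2 1.15, SE 0.48; adjusted p = 0.0471), where library size alone gave -0.23. Of 5 tested meiotic genes 4 were higher (camera adjusted p = 0.000751; 0.0395 with an estimated correlation), and HEI10, which shares reads, had log2 0.21 (SE 0.47). Of 9 tested genes in the list of RdDM machinery, which also holds TIL1, 6 with TIL1 were higher and 1 lower (camera adjusted p = 0.0484; adjusted p = 0.152 with an estimated correlation): DRD1 was 92.1-fold higher (interval 16 to 3690), NRPD1B 17.7-fold (interval 5.61 to 89.5), DCL3 7.67-fold, KTF1 5.27-fold, DMS3 4.74-fold and TIL1 4.1-fold, while SUVH9 was 52.7-fold lower (log2 -5.66, SE 0.66). AGO4 (0.77, SE 0.60) and SUVH2 (0.31, SE 0.79) were not called. Of 5 tested RdDM targets DML1 was 14.3-fold higher and FWA, a homeobox gene silenced by DNA methylation, 3.02-fold lower (log2 -1.59, SE 0.40), which MIR scaling turned to 0.49 (camera adjusted p = 0.647). The tapetum marker AMS was at least 75.8-fold higher, and AT5G07230 had 35 reads against 0 (adjusted p = 0.0885), giving 1 higher of 2 tested, or 2 adjusted over the list alone (camera adjusted p = 0.0137; adjusted p = 0.152 with an estimated correlation).

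Over the genome, edgeR with Benjamini-Hochberg adjustment called 10581 bins higher and 5760 lower in WT meiocytes (64.8% higher). Library size alone gave 7907 and 23146, MIR scaling 14457 and 1015, and removal of rDNA, organelle and structural RNA bins 8386 and 8472, so the balance of gains and losses is open, and 6943 higher and 846 lower were called in all 4 edgeR scalings (TMM, library size, MIR scaling and the removal). The median log2 value was -0.37, and -2.35, 1.03, -0.99 and -0.85 with library size, MIR scaling, DESeq2 and the removal. The intergenic gains with the smallest p were on chromosome 4 at 18482001 to 18482500 (1200-fold), chromosome 1 at 4493701 to 4494500 near DIS1 (1890-fold) and chromosome 3 at 20573901 to 20574800 (1120-fold), a region that touches the gene EXPA16. The losses with the smallest p were on chromosome 3 at 1165901 to 1166100 near SUVR4 (at least 50.8-fold) and 13589001 to 13589100 (48.4-fold, interval 13.2 to 402) and chromosome 4 at 15160901 to 15161000 (at least 39.3-fold). These were not losses of meiocytes of every genotype. Top bins in that order had 8.54, 8.96 and 9.55 CPM in pol2a meiocytes, against 12.8, 8.09 and 9.88 in WT seedlings. In suvh2suvh9 meiocytes they had 0.133, 8.28 and 0 CPM.

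What changed in pol2a meiocytes? A few genes gained small RNAs from almost none. AT1G66235 went from 1.37 CPM (SD 0.148, n = 2) to 271 CPM (SD 0.815), a 199-fold gain (log2 7.61, SE 0.49; adjusted p = 8.49e-15), and AT2G00540 from 0 reads to 1156, at least 729-fold. XTH17, which encodes a cell wall xyloglucan endotransglucosylase/hydrolase, rose 401-fold (interval 110 to 3320; 424 against 2 reads) and AT1G65483 172-fold (log2 7.36, SE 0.56). AT4G00891 (116-fold), AT2G14060 (75.8-fold), AT4G04975 (51.4-fold), AT2G13975 (38.4-fold), AT5G44770 (31.6-fold) and AT1G36360 (16.2-fold) followed. Among the losses, AT4G00960 was 53.7-fold lower (log2 -5.75, SE 0.48; adjusted p = 1.99e-11), MIR773A 20.3-fold (log2 -4.36, SE 0.46) and HOS10, a MYB gene close to MIR773A, 21.8-fold (log2 -4.46, SE 0.51). AT1G63150 (37.9-fold), AT2G14640 (36.2-fold), AT3G43970 (17.6-fold), AT4G10603 (13.3-fold), the imprinted gene MPC (13.2-fold) and AT1G34015 (10.4-fold) also fell, and AT1G62760 had 0 reads against 201.

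Of the gene lists, other MIR genes had 18 lower and 1 higher in pol2a meiocytes, or 24 and 1 adjusted over the list alone (camera adjusted p = 0.00171; adjusted p = 0.622 with an estimated correlation), among them MIR779 (log2 -3.03, SE 0.45). MIR scaling left 4 lower and 4 higher, and moved the median from -0.76 to 0.13. Conserved MIR genes had 5 lower and 2 higher, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.303). MIR162B (log2 -2.70, SE 0.37), MIR161 (-1.64, SE 0.37), MIR156A (-1.88, SE 0.37), MIR403 (-1.43, SE 0.36) and MIR396B (-1.31, SE 0.36) were lower, and MIR159C (1.87, SE 0.42) and MIR157B (6.18, SE 1.60) higher. Under MIR scaling the calls of MIR156A, MIR161, MIR403 and MIR396B were lost, with log2 values of -0.90, -0.66, -0.46 and -0.33, and MIR403 had 0.37 with 24 nt reads alone. As this scaling measures MIR genes against their own sum, a loss common to them would not show in it. Of the 8 TAS genes TAS1C was 3.02-fold lower (log2 -1.58, SE 0.37; adjusted p = 0.0051), lost under MIR scaling (-0.60), and 2 were lower adjusted over the list alone (camera adjusted p = 0.303); TAS2 had log2 -1.01 (SE 0.36). RBCS1B was the 1 green tissue marker called higher, 7.09-fold (log2 2.75, SE 0.77), with 3 higher adjusted over the list alone (camera adjusted p = 0.00171; adjusted p = 0.518 with an estimated correlation). FWA went from 95 to 16 reads, 3.14-fold lower (log2 -1.64, SE 0.50; adjusted p = 0.049), a call that was lost under DESeq2 (-1.48) and library size (-1.72) and without any 1 of the 4 libraries. Of RdDM machinery, meiotic and tapetum genes edgeR called 0, with 1, 1 and 0 at an unadjusted p under 0.05 and 0 in each list with DESeq2. DMC1 had log2 -1 (SE 0.45), ZYP1a -0.49, ASY1 -0.57 and AMS 0.66 (SE 0.42).

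Over the genome 928 bins were called higher and 1067 lower (46.5% higher). The balance moved with scaling: 585 and 2210 with library size, 1641 and 526 with MIR scaling, 796 and 1878 with DESeq2, and 460 and 3785 with rDNA, organelle and structural RNA bins removed. In all 4 edgeR scalings, DESeq2 left aside, 390 bins were higher and 499 lower. The median log2 value was -0.12, and -0.60, 0.33, -0.25 and -0.74 in that order. At gene level 129 were higher and 451 lower, against 508 and 109 with MIR scaling. Without the first or second WT library 735 and 838 bins and 286 and 264 genes were called, and without the first or second pol2a library 751 and 735 bins and 195 and 169 genes, against 1995 bins and 580 genes with all. With neighbouring bins joined into loci, the 76 windows of 1 Mb with at least 50 loci were compared with permutations, and smaller windows were left out. Of the 76, 3 held a larger share of loci called in these 4 scalings than 95% of permutations gave. They were chromosome 1 from 24 Mb, where 21% of 252 tested bins were called (32 higher and 21 lower), chromosome 1 from 25 Mb, with 7.1% of 210, and chromosome 2 from 2 Mb, with 10.8% of 730. These windows held 147 of the 889 bins. By bins alone no other window came near 21%, but chromosome 3 from 3 Mb, with 11.8% of 85, was above both of the others. Also above chromosome 1 from 25 Mb were chromosome 4 from 0 Mb, with 8.2% of 328, and chromosome 3 from 6 Mb. The same held for chromosome 1 from 12, 13, 23 and 27 Mb. XTH17, AT1G65483 and AT1G66235 lie in the window on chromosome 1 from 24 Mb. So do the regions at 24223701 to 24224100 (2790-fold higher, interval 500 to 110000) and 24258601 to 24259300 next to XTH17 (at least 552-fold higher). The third region that rose was on chromosome 1 at 23149101 to 23149800 (102-fold). Regions that fell lay on the same chromosome at 23932201 to 23932400 (94.4-fold), 18788201 to 18788500 near AUG4 (57.7-fold) and 12263001 to 12263700 near GXMT1 (21.2-fold). Structural RNA bins had 40 higher and 5 lower (camera adjusted p = 0.00224; adjusted p = 0.884 with an estimated correlation), and intergenic bins 438 and 714 (camera adjusted p = 0.522).

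**Figure D3:**
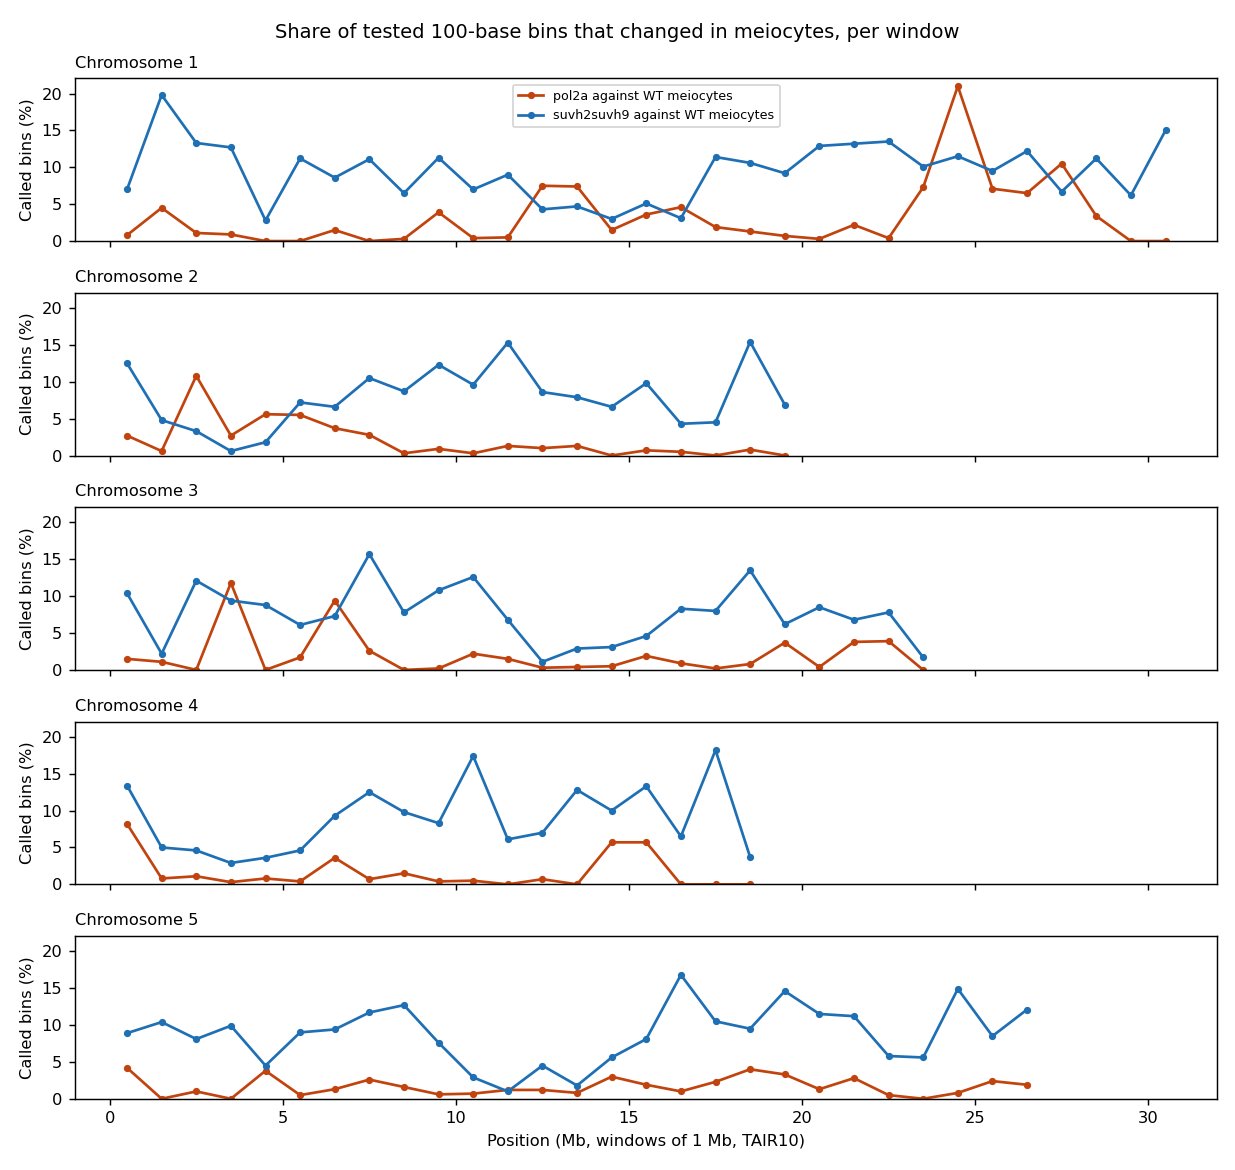
Percent of tested bins called in all 4 edgeR scalings in each 1 Mb window of the 5 chromosomes, for pol2a (orange) and suvh2suvh9 (blue) meiocytes against WT meiocytes.

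What changed in suvh2suvh9 meiocytes? Bins with losses outnumbered those with gains, and the losses with the smallest p were in a cluster of glycosyl hydrolase genes on chromosome 2. GH9B10 went from 326 reads to 0, at least 92.7-fold lower (adjusted p = 2.88e-10), GH9B9 from 218 to 0, at least 62-fold, and GH9B12 from 167 to 0, at least 47.5-fold. AT3G20690 (174-fold, interval 30.9 to 6900), AT1G07233 (129-fold, interval 22.8 to 5120), AT5G21125 (87.5-fold), AT1G19410 (66.9-fold, interval 18.2 to 558), AT2G24761 (at least 33.5-fold), AT1G31163 (30.3-fold; log2 -4.86, SE 0.51) and AT5G38975 (14.6-fold) also fell. FWA fell 27-fold, from 95 to 3 reads (interval 8.96 to 133; adjusted p = 3.73e-06). Among the gains, HAK5, which encodes a high-affinity potassium transporter, rose 11.7-fold (log2 3.61, SE 0.39; 33478 against 3361 reads) and AT5G44770 32.9-fold (log2 4.97, SE 0.44). AT3G00670 (34.2-fold), AT2G11430 (6.28-fold), AT1G57710 (5.59-fold), AT3G45340 (17.6-fold, interval 4.46 to 152), AT2G16490 (3.61-fold), the cold-induced gene KIN2 (4.5-fold; log2 2.10, SE 0.44), AT3G15450 (32.1-fold) and the snoRNA AT1G06247 (3.43-fold, all reads shared) were the other gains. Without the first suvh2suvh9 meiocyte library the log2 value of AT3G15450 went from 4.79 to 2.31 and that of KIN2 to 1.48, and their calls were lost.

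Among the lists of suvh2suvh9 meiocytes, other MIR genes had 27 lower and 0 higher, or 32 and 0 adjusted over the list alone (camera adjusted p = 1.08e-06; adjusted p = 0.486 with an estimated correlation), with 15 lower and a median of -0.44 in place of -1 under MIR scaling. MIR5635B was among them (log2 -3.70, SE 0.61). Conserved MIR genes had 3 lower (MIR161, MIR156B and MIR399C) and 2 higher (MIR162A and MIR395F), or 4 and 2 adjusted over the list alone (camera adjusted p = 0.164). RBCS1A was 2.68-fold higher (log2 1.39, SE 0.39; adjusted p = 0.0194), the 1 green marker called, with 2 adjusted over the list alone (camera adjusted p = 0.0251; adjusted p = 0.486 with an estimated correlation). FWA was the 1 RdDM target called, with 2 lower adjusted over the list alone, and DML1 had log2 -1.28 (SE 0.53). Of TAS, RdDM machinery, meiotic and tapetum genes edgeR called 0, with 0, 1, 1 and 1 at an unadjusted p under 0.05 and 0 in each with DESeq2. ZYP1a had log2 -1.52 (SE 0.51), AMS 1.19 (SE 0.41) and TAS1C -0.50 (SE 0.36).

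Over the genome 670 bins were higher and 3170 lower (17.4% higher). MIR scaling gave 728 and 2604 and library size 565 and 3061, and 303 higher and 2562 lower were called in all 4 edgeR scalings. The median of -0.28 moved to -0.15 with MIR scaling and to -0.44 with DESeq2. At gene level 142 were higher and 678 lower, but library size gave 401 and 467 and MIR scaling 389 and 361. Intergenic bins had 2521 lower and 258 higher (median log2 -0.62; camera adjusted p = 5.69e-06; adjusted p = 0.145 with an estimated correlation), and chromosome arms 2288 lower and 266 higher (camera adjusted p = 0.00465; adjusted p = 0.145 with an estimated correlation). Regions that fell were on chromosome 5 at 5749101 to 5749400 (at least 80.5-fold) and 10127801 to 10127900 (at least 43.7-fold) and chromosome 2 at 1695901 to 1696000 (at least 38.2-fold). Regions that rose were on chromosome 4 at 6281501 to 6282700 (51-fold), chromosome 3 at 13589001 to 13589100 (49.2-fold, interval 13.1 to 415) and chromosome 1 at 1592101 to 1592600 near OFP12 (29.2-fold). At the region from 13589001 only WT meiocytes were low, with 0.173 CPM against 8.09 to 15.8 in the other groups. The number of calls depended on the library: 2249 and 2412 bins without the first or second WT library, 1849 without the first mutant library and 3667 without the second, against 3840. For genes these counts were 504, 521, 316 and 1143, against 820.

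Did pol2a also act in seedlings? Changes were few there. The pseudogene AT4G13470, next to SUVH9, went from 0 to 658 reads (at least 139-fold; adjusted p = 2.07e-08), and the non-coding AT1G06393 rose at least 121-fold. LCR26 (79.6-fold, interval 14 to 3170), AT1G70080 (at least 61.7-fold), AT4G10160 (36-fold, interval 9.75 to 301), AT1G64035 (at least 21.1-fold), AT2G27229 (at least 16.6-fold), AT1G68780 (15-fold), U6.4 (at least 11.2-fold) and HAK5 (3.59-fold; log2 1.83, SE 0.40) also rose. AT3G22955 was 196-fold lower (log2 -7.51, SE 0.61; adjusted p = 1.21e-09), AT5G46295 188-fold (interval 33.1 to 7500), AT1G19830 98.9-fold (interval 26.8 to 825), AT3G30730 64.9-fold (interval 17.4 to 545), scpl5 18.6-fold, SUVH9 17.9-fold, the cytochrome P450 gene CYP71A20 15.3-fold (log2 -3.92, SE 0.46), AT5G11370 6.77-fold, MIR159C 6.05-fold (log2 -2.59, SE 0.38) and AT4G04221 5.18-fold. Calls of AT1G68780, AT1G70080, AT2G27229, AT4G04221, AT5G11370, HAK5, U6.4 and scpl5 were lost without at least 1 library.

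Conserved MIR genes had 3 lower in pol2a seedlings, MIR159C, MIR398A (log2 -1.67, SE 0.39) and MIR166G, or 8 adjusted over the list alone (camera adjusted p = 7.71e-07; adjusted p = 0.299 with an estimated correlation). Their median of -0.42 became 0.16 under MIR scaling. SUVH9 was the 1 RdDM machinery gene called. Of other MIR genes edgeR called 0, with 15 at an unadjusted p under 0.05 and 3 lower with DESeq2 (camera adjusted p = 0.00474; adjusted p = 0.564 with an estimated correlation). Of RdDM targets, TAS, green, meiotic and tapetum genes it called 0, with 2, 0, 1, 1 and 0 at an unadjusted p under 0.05 and 0 in each with DESeq2, while 1 RdDM target was higher and 1 lower adjusted over the list alone. The green markers had a median log2 of 0.42 (camera adjusted p = 0.00293; adjusted p = 0.299 with an estimated correlation). Over the genome 79 bins were higher and 87 lower (47.6% higher), against 69 and 112 with library size, 93 and 62 with MIR scaling and 69 and 116 with the removal of rDNA, organelle and structural RNA bins. The median of 0.20 became -0.01 with library size and 0.39 with MIR scaling. Without the first pol2a seedling library 352 bins were called, without the second 80, and without the first or second WT library 98 and 137. Genes numbered 12 higher and 39 lower, with 19 and 9 under MIR scaling, and 23, 26, 41 and 21 genes were called without the first or second WT or the first or second pol2a library. Structural RNA bins had 0 calls and a median of -0.40 (camera adjusted p = 3.79e-16; adjusted p = 0.724 with an estimated correlation). Regions that rose lay on chromosome 1 at 12517401 to 12517500 (562-fold, interval 155 to 4650), chromosome 3 at 2251301 to 2251600 (317-fold) and in the rDNA of chromosome 3 (142-fold), and regions that fell on chromosome 4 at 10860401 to 10860500 (at least 182-fold), chromosome 5 at 18780101 to 18780400 (at least 171-fold) and chromosome 2 at 11834901 to 11835000 (at least 107-fold). The top rDNA bin was low in WT seedlings, at 0.161 CPM against 68.2 in WT meiocytes.

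What was lost in suvh2suvh9 seedlings? More bins were called than in the other mutant comparisons with WT, and most of those lower were intergenic. AT3G20690 fell 797-fold (interval 143 to 31500; adjusted p = 7.34e-13), GH9B12 597-fold (interval 107 to 23600), AT1G19410 510-fold (interval 91.2 to 20200), GH9B10 374-fold (interval 103 to 3100) and AT3G26870 372-fold (interval 103 to 3080). AT5G42930 fell 244-fold (log2 -7.84, SE 0.56), CNGC13, a cyclic nucleotide-gated channel gene, at least 168-fold, AT1G07233 at least 166-fold, AT3G06835 119-fold and AT4G03380 66.9-fold (log2 -6.01, SE 0.47). FWA went from 400 reads to 2, a 155-fold loss (interval 42.7 to 1290; adjusted p = 3.76e-11). Gains included MIR156A at 8.92-fold (log2 3.24, SE 0.39; adjusted p = 1.4e-08), MIR156C at 6.01-fold (log2 2.62, SE 0.39) and MIR156F at 17.7-fold, which shares reads with AT5G26146. MIR156 keeps plants juvenile by repressing SPL genes. MIR5020A (at least 123-fold), AT5G07745 (24.5-fold), AT3G00580 (12.9-fold), PYK10, a beta-glucosidase gene of ER bodies (9.64-fold; log2 3.36, SE 0.53), and the chloroplast 16S rRNA genes rrn16S (4.9-fold) and ArthCr088 (4.82-fold) rose too.

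Conserved MIR genes split in suvh2suvh9 seedlings, with 7 higher and 17 lower, or 11 and 19 adjusted over the list alone (camera adjusted p = 0.842). MIR156A, MIR156C, MIR156F, MIR156G, MIR157A (log2 2.56, SE 0.42), MIR157B (2.48, SE 0.42) and MIR159C (1.23) were higher, and MIR163 (-2.72, SE 0.40), MIR319A (-2.33, SE 0.39, but 1.57 with bins assigned by midpoint), MIR393B (-2.02), MIR396B (-2.02) and MIR395F (-4.90) were among the lower ones. Other MIR genes had 36 lower and 5 higher, or 41 and 5 adjusted over the list alone (camera adjusted p = 0.0054; adjusted p = 0.613 with an estimated correlation), with MIR5635B at -4.77 and MIR5644 at -6.32. Of 8 TAS genes TAS1A, TAS1B, TAS1C and TAS2 were lower (log2 -0.98, -1.06, -1.52 and -0.98; TAS1A had 0.26 with 24 nt reads alone), with 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.427), and MIR scaling left 1 lower and 1 higher. Tested as bins, TAS loci pointed the other way, with 5 of 34 bins higher, 0 lower and a median of 0.59. Camera gave these bins an adjusted p of 2.72e-05, upward, and 0.22 with an estimated correlation. The direction at TAS genes is therefore open. KTF1 was 3.87-fold higher and SUVH9 10.4-fold lower in the RdDM machinery, FWA was the 1 RdDM target called, and HEI10, which shares reads, was 4.55-fold lower among meiotic genes. Of green and tapetum genes edgeR called 0, with 1 and 0 at an unadjusted p under 0.05 and 0 in each with DESeq2.

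Over the genome 4300 bins were higher and 11134 lower (27.9% higher). Gains depended on scaling, at 294 with library size, 1021 with MIR scaling, 1288 with DESeq2 and 1817 with the removal, against 21878, 16577, 11390 and 13779 losses, and 95 higher and 11015 lower were called in all 4 edgeR scalings, DESeq2 left aside. The median was -1.12, and -2.90, -1.95, -1.61 and -1.45 in that order. Intergenic bins had 8916 lower and 949 higher, with a median of -2.41 (camera adjusted p = 3.34e-16; 0.00541 with an estimated correlation), and the medians in the other scalings were all lower still. Chromosome arms had 7726 lower and 1628 higher with a median of -2.43 (camera adjusted p = 7.16e-07; 0.016 with an estimated correlation), while pericentromeres had 3404 and 1585 and a median of -0.29, higher than that of other bins (camera adjusted p = 0.0115, upward; adjusted p = 0.127 with an estimated correlation). MIR bins had a median of 0.57 (camera adjusted p = 1.01e-08, and 0.016 with an estimated correlation). This median became -0.44 under MIR scaling, -1.38 with library size and -0.13 with DESeq2. In the TMM fit of genes, conserved and other MIR genes had medians of -0.29 and -0.91. The upward direction therefore rests on the TMM fit of bins. Genes numbered 404 higher and 2013 lower, or 68 and 3302 with library size. Regions that fell were on chromosome 4 at 12957101 to 12957400 (at least 244-fold), chromosome 1 at 11740601 to 11740900 near IDH-IV (at least 132-fold) and chromosome 3 at 10899101 to 10899200 near RLP43 (122-fold). The gains with the smallest p lay in the rDNA of chromosome 3 (374-fold in 1 bin), on chromosome 5 at 23774701 to 23775100 (70.9-fold) and on chromosome 3 at 13769101 to 13769200 (17.6-fold). That rDNA bin was also the top rDNA bin of pol2a seedlings, so both gains rest on the 0.161 CPM of WT seedlings. WT, pol2a and suvh2suvh9 meiocytes had 68.2, 3.6 and 49.4 CPM there. Without the first mutant library 7123 bins were called and without the second 9893, and without the first or second WT library 10187 and 11388.

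How do the mutants differ from each other? In meiocytes AT1G66235 was 425-fold higher in pol2a than in suvh2suvh9 (log2 8.68, SE 0.53; adjusted p = 4.41e-15), AT2G00540 1860-fold (interval 334 to 73700) and AT1G65483 257-fold, while MPC was 24.1-fold lower (log2 -4.67, SE 0.46), AT4G00960 12.9-fold and AT4G10603 12.6-fold. In seedlings AT3G20690 (652-fold, interval 117 to 25800), GH9B12 (614-fold, interval 110 to 24300) and GH9B10 (331-fold, interval 91.6 to 2740) were higher in pol2a, and MIR5020A was 97.2-fold lower (log2 -6.46, SE 0.62), MIR156F 49.9-fold and MIR159C 14-fold. In meiocytes 3502 bins were higher and 1409 lower in pol2a (71.3% higher), but 2473 and 2583 with library size, 4766 and 818 with MIR scaling and 2433 and 4411 with the removal. In seedlings 12318 were higher and 3222 lower (79.3% higher), against 22542 and 324 with library size, 19655 and 600 with MIR scaling and 11459 and 1280 with DESeq2. Without single libraries the seedling count was 11981 and 10049 (first and second pol2a) and 7107 and 10034 (first and second suvh2suvh9). In meiocytes it was 2697, 2308, 3491 and 4134 in the same order.

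Did the mutants hit the same places? In meiocytes 141 bins were higher in both, where independence gives 15.7, and 187 were lower in both, where it gives 85.4. Simulated unchanged groups against the same WT libraries shared 1.35 and 0.55, but had a mean of only 7.2 and 8.8 called bins, so these give no chance count for longer lists. The log2 changes of the mutants had a covariance of 1.387 and a correlation of 0.24, against 0.644 and 0.35 in the simulations, so part of the excess may come from shared controls. In seedlings 76 bins were lower in both, where independence gives 24.5, and 13 higher, where it gives 8.6. Library size gave 5 higher against 0.5, and the fit without the first WT seedling library 9 against 1.5, so an excess of shared gains in seedlings depends on the setting. The simulations of seedlings shared 0.7 higher and 0.85 lower from lists of 19.1 and 7.8 bins, and the covariance was 0.839 and the correlation 0.25, against 0.362 and 0.39. Without the first or second WT meiocyte library the 141 bins became 37 and 39, without the pol2a libraries 54 and 72, and without the suvh2suvh9 libraries 108 and 190, and in the same order the 187 became 111, 116, 81, 63, 190 and 282. For seedling libraries in that order the 13 became 9, 15, 16, 8, 6 and 11, and the 76 became 43, 53, 75, 27, 45 and 77. The sharing of calls between tissues was added after the data had been seen. For suvh2suvh9, 2817 bins were lower and 324 higher in both tissues (independence 891.1 and 72.7; r = 0.57). Library size gave 2883 lower and 33 higher in both (1690.9 and 4.2), so the number of shared gains depends on the scaling. For pol2a, 10 were higher in both tissues, where independence gives 1.9, and 3 lower, where it gives 2.3. Another 8 were lower in meiocytes and higher in seedlings (2.1), and over all bins r was 0.02. The counts under independence take bins as separate although called bins come in runs, so all were repeated with neighbouring bins joined into loci. In meiocytes 67 loci held a gain in both mutants against 9.9, and 178 a loss against 99.6. The same bin was called in 57 and 136 of them. Opposite directions were also met: 25 loci held a loss in pol2a and a gain in suvh2suvh9 against 13, and 61 the reverse against 75.4. Here the same bin was called in 4 and 12. By loci, an excess was thus not confined to shared directions. In seedlings 10 loci held a gain in both mutants against 7.1 and 61 a loss against 34.5. For pol2a between tissues 8 loci were higher in both against 1.9 and 5 lower against 3, but 8 rose in meiocytes and fell in seedlings against 2.3, and 12 the reverse against 2.6, so no shared direction was seen. Loci with more bins have more chances to be called, which raises such counts too.

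Which changes differed between tissues? The gain of AT1G66235 in pol2a was larger in meiocytes by 6.91 log2 units (SE 0.65; adjusted p = 4.73e-09) and that of AT2G00540 by 13.94 (SE 1.68). AT3G22955 differed by 7.26 (SE 0.77), AT4G00960 by -5.62 (SE 0.61), MIR773A by -4.68 (SE 0.59) and AT1G62760 by -10.66 (SE 1.35). AT2G00540 had 0 reads in WT meiocytes and AT1G62760 0 in pol2a meiocytes, so their values are fitted ones without an exact size. For suvh2suvh9 the loss at AT5G42930 was weaker in meiocytes by 7.33 (SE 0.68; adjusted p = 2.5e-09), and AT4G10210 differed by 10.38 (SE 1), fitted against 0 reads in suvh2suvh9 seedlings, with AT4G10201, which shares its reads, at 6.7 (SE 0.7). MIR156A differed by -3.89 (SE 0.52), and AT5G53905 and U3B, which share all reads, by -3.27 (SE 0.52). In all 699 bins were called for pol2a, 163 higher and 536 lower, with 170 and 237 under MIR scaling, and 1106 for suvh2suvh9, 658 higher and 448 lower, with 6313 and 85 under library size and 3335 and 147 under MIR scaling. Both counts moved when 1 library was left out. For pol2a they were 296 and 311 (first and second WT meiocyte library), 309 and 222 (pol2a meiocyte), 390 and 560 (WT seedling), and 1622 and 397 (pol2a seedling). For suvh2suvh9 they were 550 and 457, 2010 and 771 (suvh2suvh9 meiocyte), 874 and 1017, and 503 and 559 (suvh2suvh9 seedling).

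**Figure D4:**
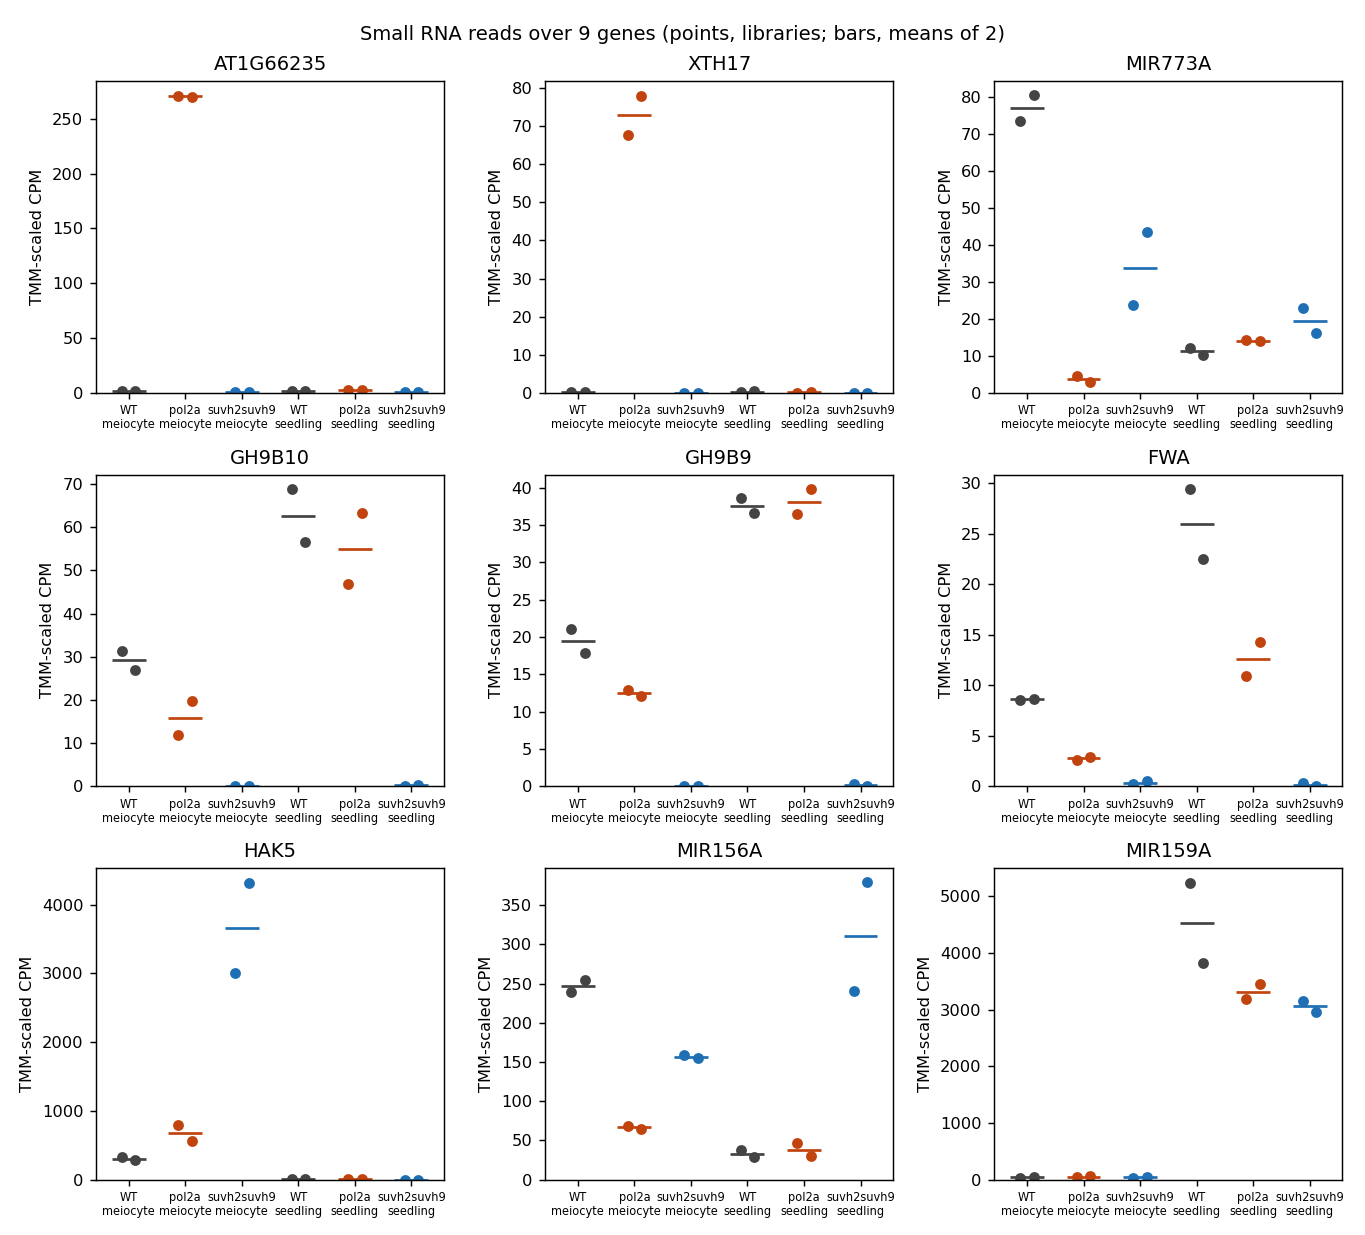
TMM-scaled CPM of 9 genes in each library.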

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

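The tissue differences given first were planned, and the tests of the patterns after them were chosen after the values had been seen. For pol2a, 699 bins had a change that differed between meiocytes and seedlings, with AT1G66235 at 6.91, AT3G22955 at 7.26, AT2G00540 at 13.94, AT4G00960 at -5.62, MIR773A at -4.68 and AT1G62760 at -10.66 log2 units. For suvh2suvh9, 1106 bins differed, with AT5G42930 at 7.33, AT4G10210 at 10.38, AT4G10201 at 6.7, MIR156A at -3.89, and AT5G53905 and U3B at -3.27 each. The values of AT2G00540, AT1G62760 and AT4G10210 are fitted ones against a group with 0 reads and give no exact size.

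In meiocytes of both mutants 23 nt reads gained on 24 nt reads: their ratio was 0.254 in WT, 0.678 in pol2a (2.67-fold) and 0.515 in suvh2suvh9 (2.03-fold), though the suvh2suvh9 libraries stood apart at 0.629 and 0.4. A higher ratio was not confined to meiocytes: suvh2suvh9 seedlings had 0.442 against 0.322 in WT seedlings, and pol2a seedlings had 0.313. In suvh2suvh9 seedlings the 20 to 21 nt ratios were 2.01-fold higher at MIR and 4.83-fold at TAS genes. Such ratios, here and in meiocytes, pool the reads of all MIR or all TAS genes. A shift in which of these genes have reads can move them too, which was not tested, and MIR156 genes rose in suvh2suvh9 seedlings. But their share of 23 nt reads fell (9.66% against 14%), where it rose in pol2a (27.2%) and suvh2suvh9 (23.7%) meiocytes (WT 15.1%). Their 23 to 24 nt ratio rose mainly in chromosome arms (0.62 against 0.338) and little in pericentromeres (0.362 against 0.304). In meiocytes this ratio rose in both, to 0.64 and 0.747 in pol2a and 0.483 and 0.572 in suvh2suvh9 (WT 0.244 and 0.272). A change of the 24 nt pathway alone is argued against by MIR genes, where the ratio of 20 to 21 nt reads rose 1.96-fold in pol2a. Chloroplast reads rose in both mutants, but admixture of green seedling-like tissue is argued against: WT meiocytes mixed with seedlings of the mutant as far as these reads allow would reach 0.263 at most (other tissues were not tested). Loss of end nucleotides from MIR, TAS and 24 nt small RNAs alike may be at work, as the lowest of the 4 folds of the 20 to 21 nt ratio at MIR and TAS genes was 1.68, but rDNA reads of pol2a meiocytes became longer (19 nt 14.8% against 19.2%, 26 nt 7.85% against 5.1%), and whether such a loss arose in the cells or during RNA preparation stays open.

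Reads of 23 to 24 nt took a smaller share of the library in pol2a meiocytes (23.2% against 53.2% in WT) and in suvh2suvh9 seedlings (4.69% against 22.9%). In pol2a meiocytes their number per MIR read was 0.987 times that of WT, while rDNA reads per MIR read were 5.35-fold higher, which is in line with rRNA fragments taking up reads. They are unlikely to be mainly 24 nt siRNAs: 9.34% of the gained rDNA reads were 24 nt long, against at least 38.5% of nuclear reads outside rDNA, although this length rose from 6.92% to 8.89% of rDNA reads. In suvh2suvh9 seedlings rDNA reads per MIR read were 3.17-fold higher, but the 23 to 24 nt reads per MIR read were 0.431 times those of WT, so rRNA fragments are not the whole cause there. Open is whether MIR reads themselves stayed level, as no added standard was used here, and why rRNA fragments rose.

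Bins that changed in pol2a meiocytes were uneven along the chromosomes. Of 76 windows with at least 50 loci, 3 were above 12.5% of loci called, the limit that 95% of permutations stayed under. Of these 3, 1 on chromosome 1 from 24 Mb was above the highest permuted value (18.3% against 16%). But the 3 windows held 147 of the 889 bins, so most changed bins lay elsewhere. An even spread over loci of equal chance is argued against by a spread of called loci 3.94 times that expected, where the highest of 1000 permutations gave 1.74. But suvh2suvh9 meiocytes (5.94) and seedlings (20.75) were uneven too, so this does not set pol2a apart. Loci with more bins have more chances to be called, which the permutations did not take into account. For the 76 of these 147 bins with enough seedling reads, a sequence background that pol2a seedlings share is argued against. Their median change in pol2a seedlings, signed by the meiocyte change, was -0.24. The other bins had too few seedling reads to tell. Among the places without seedling reads were the regions from 24223701 and 24258601 on chromosome 1, with a top bin at 0 CPM in WT and pol2a seedlings. A background of the meiocyte plants alone could not be told from an effect of the mutation: 42.2% of the changed bins in the windows were higher, and the direction does not separate these cases.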

How the results depend on the processing

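Fits on 24 nt reads, on 21 to 22 nt reads and with rDNA, organelle and structural RNA bins removed, and calls shared between tissues, were chosen after seeing the data, and the other settings before. Numbers are called bins or genes, with the value of the report first. Windows of 500 bases were not applied to genes, and DESeq2 gave no adjusted p for 25 named genes.

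In pol2a meiocytes 1995 bins became 3090 with the libraries of that tissue alone, 4245 with rDNA, organelle and structural RNA removed, 1091 with 21 to 22 nt reads, 1045 windows of 500 bases, and 735 to 838 without 1 library. In suvh2suvh9 meiocytes 3840 became 1700 with that tissue alone, 1577 with 24 nt reads, 645 with 21 to 22 nt reads, and 1849 to 3667 without 1 library. In pol2a seedlings 166 became 347 without a filter, 102 with the strict filter, 301 with 24 nt reads, 89 with 21 to 22 nt reads, 83 windows, and 80 to 352 without 1 library. In suvh2suvh9 seedlings 15434 became 6512 with the strict filter, 2431 with 21 to 22 nt reads, and 7123 to 11388 without 1 library.

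Between the mutants, 4911 bins in meiocytes became 3039 without a filter, 2186 with 24 nt reads, 1392 with 21 to 22 nt reads, and 2308 to 4134 without 1 library. The 15540 in seedlings became 6919 with the strict filter, 3816 with 21 to 22 nt reads, and 7107 to 11981 without 1 library. Between WT tissues 16341 became 31053 with library size, 10526 with the strict filter, 7715 with 21 to 22 nt reads, 8022 windows, and 13256 to 14117 without 1 library. The tissue difference of pol2a (699) became 1374 with DESeq2, 407 with MIR scaling, 1430 without a filter, 1189 with the strict filter, 1576 with rDNA, organelle and structural RNA removed, 276 with 21 to 22 nt reads, 350 windows, and 222 to 1622 without 1 library. That of suvh2suvh9 (1106) became 2046 with DESeq2, 6398 with library size, 3482 with MIR scaling, 454 with 21 to 22 nt reads, and 457 to 2010 without 1 library.

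For genes, 580 in pol2a meiocytes became 275 with 21 to 22 nt reads and 169 to 286 without 1 library. In suvh2suvh9 meiocytes 820 became 362 with 24 nt reads, 233 with 21 to 22 nt reads, and 316 to 1143 without 1 library. In pol2a seedlings 51 became 107 with DESeq2, 32 with library size, 28 with MIR scaling, 20 with the strict filter, 103 with that tissue alone, 31 with 24 nt reads, 8 with 21 to 22 nt reads, and 21 to 41 without 1 library. In suvh2suvh9 seedlings 2417 became 855 with 21 to 22 nt reads and 1665 to 2232 without 1 library. Between mutants in meiocytes 831 became 1258 with library size, 517 with 24 nt reads, 335 with 21 to 22 nt reads, and 482 to 842 without 1 library. In seedlings 2255 became 3499 with library size, 751 with 21 to 22 nt reads, and 1572 to 2007 without 1 library. Between WT tissues 5616 became 2277 with the strict filter, 1819 with 24 nt reads, 1940 with 21 to 22 nt reads, and 4428 to 5056 without 1 library. The tissue difference of pol2a (277) became 136 with MIR scaling, 92 with 21 to 22 nt reads, and 58 to 227 without 1 library, and that of suvh2suvh9 (634) became 1970 with library size, 336 with 24 nt reads, 268 with 21 to 22 nt reads, and 338 to 844 without 1 library.

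Directions reversed in single genes: MIR403 in pol2a meiocytes (-1.43 to 0.37) and TAS1A in suvh2suvh9 seedlings (-0.98 to 0.26) with 24 nt reads, FWA between WT tissues with MIR scaling (-1.59 to 0.49), TASIR-ARF between WT tissues with library size (1.15 to -0.23), and MIR319A in suvh2suvh9 seedlings with bins assigned by midpoint (-2.33 to 1.57). Among shares, the difference of structural RNA in suvh2suvh9 meiocytes went from -1.31 to 1.17 points by midpoint. Without organelle and structural RNA reads the WT tissue difference of pseudogenes went from 1.07 to -0.692, that of protein-coding genes from 2.28 to -0.537 and that of pericentromeres from 4.49 to -7.19, with the groups apart both times for the last. The intergenic difference in suvh2suvh9 meiocytes went from -1.66 to -3.69 by midpoint, and to -3.24 and -0.0934 without 1 library. In suvh2suvh9 seedlings it went from -13.1 to -18.2 by midpoint and -18.9 without organelle and structural RNA reads, and to -15 and -11.2 without 1 library. Between WT tissues it went from 33.5 to 30.4 and 29.9, and 31.6 to 35.4 without 1 library. Without 1 library it lay between -2.53 and 1.49 in pol2a seedlings (-3.13 by midpoint, -0.52 in the report's classes) and between -26.1 and -25 in pol2a meiocytes.

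The intergenic set of suvh2suvh9 meiocytes went from p = 5.69e-06 with camera to 0.145 with an estimated correlation, both adjusted. The fry test, which asks whether a set moves 1 way on balance and not whether it moves more than other bins, gave unadjusted p = 0.0944 upward in pol2a seedlings (camera adjusted p = 0.51, downward) and 6.55e-05 upward between WT tissues (0.377, upward). Bins shared by the mutants in meiocytes went from 141 higher to 91 and from 187 lower to 326 with library size, and to 37 to 190 and 63 to 282 without 1 library. In seedlings 13 higher became 5 with library size, and 6 to 16 without 1 library, and 76 lower became 27 to 77.

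With replicate number as a block, bins shared and higher in seedlings went from 13 to 20 (8.1 under independence) and shared loci from 10 to 16 (7.1 both times), and pol2a meiocytes had 1852 called bins. No pairing by replicate number was seen: differences between replicates correlated at -0.076 to 0.108 over 15 pairs of groups. The highest value was that of WT and suvh2suvh9 seedlings. Such values do not exclude a shared day or batch.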

Other observations

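The tests in this part were chosen after the values had been seen. Several genes near SUVH9 were called, in different directions. Of 12259 genes tested over the genome, 32 lay within 100 kb of it. They held 4 of the 51 genes called in pol2a seedlings: CYP71A20 (log2 -3.92) and SUVH9 (-4.14) were lower, and HAK5 (1.83) and AT4G13470 were higher. In pol2a meiocytes 2 of the 32 were called, near the share over the genome (580 of 12259): HAK5 was higher (1.18) and AT4G06105 lower (-1.78). In suvh2suvh9 meiocytes 6 of the 32 were called, against 820 of 12259 over the genome. HAK5 was higher (3.61) and AT4G13470 (-7.84), AT4G13577 (-3.34), AT4G06120 (-2.33), AT4G13575 (-1.73) and AT4G13495 (-1.63) were lower. In suvh2suvh9 seedlings 11 of the 32 were called, against 2417 of 12259 over the genome. All 11 were lower, among them HAK5 (-2.66) and CYP71A20 (-6.89). MIR3932B, also among the 11, lies within AT4G13575 and shares its reads. AT4G06120 and AT4G13575, called in suvh2suvh9 meiocytes and seedlings, touch the same bin. Such genes are not separate counts. Within 100 kb of TIL1 or SUVH2 the pol2a comparisons with WT had 0 called genes, of 18 and 26 tested (edgeR). By the shares over the genome few calls would be expected among so few genes, so this does not set these places apart. The suvh2suvh9 comparisons had 3 called genes near TIL1 and 1 near SUVH2 in each tissue.

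The mutants shared a gain at AT5G44770 in meiocytes, 31.6-fold in pol2a and 32.9-fold in suvh2suvh9. Replicates of suvh2suvh9 meiocytes differed over 8-fold at 48 siRNA bins in the direction of the first library and at 7 in the other, against 0 in WT and pol2a meiocytes.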
